A study of Rattus norvegicus with 4 samples.

How the data were processed

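Bulk RNA-seq was made from synovium of rats with osteoarthritis, with 1 library from tissue that received human AdMSCs, 1 from tissue that received human SyMSCs and 2 from tissue that received PBS. Per the labels' protocols, total RNA was extracted with an RNeasy kit, messenger RNA was captured with oligo-dT beads and fragmented, complementary DNA was primed with random hexamers and its second strand marked with dUTP, and libraries were sequenced on a BGISEQ-500. The titles pair the libraries by the words Ad and Sy and call the PBS libraries "mix", a word the labels do not explain; the treatment label was used for the groups. The series title speaks of tissue before and after injection, while the treatment label of those libraries is PBS.

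The deposited values are TPM, per the file header, with 2 decimals; the columns share 1 fixed sum over the 17899 rat genes of the table, so the authors' scaling was over rat genes alone. Per the submitters' processing notes, HISAT2 2.0.4 and the genome build Rnor_6.0 were used, with no role or order stated. The counting tool, the annotation release, the use of strand and any step that separated rat from human reads are not given in the sources used here. TPM keeps no read depth, so a value of 0 has no known limit and small values are imprecise by an unknown amount. In TPM a rise of abundant genes lowers all others, and a gain of 1 cell type lowers the share of the rest.

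No genome of this build was used, so no coordinates are given. Gene symbols and NCBI Gene IDs are those of the table; 16718 of 17899 IDs were found in a RefSeq gene table of the assembly GRCr8, which was used for names alone. 10 rows had a symbol that occurs more than once (the row with the higher mean kept it), 10 rows were 0 in every library and 23 symbols had been turned into dates by a spreadsheet. No sample column was left unused. For Col1a2 the symbol's row lay near 0 TPM, so no level of that collagen is given; the row was still counted and tested as a member of the collagen list.

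The design had been written for counts, with TPM as its second choice, and that second choice was followed. Values were taken as log2(TPM + 1). Genes with at least 1 TPM in at least 2 libraries (13371) were tested with limma 3.58.1 in R 4.3.3 (eBayes with trend and robust options), injected (n = 2) against PBS (n = 2), with 2 residual degrees of freedom and Benjamini-Hochberg adjustment; a gene was called at an adjusted p under 0.05. The same test was run with 3 groups (1 residual degree of freedom) and between the Sy-titled and Ad-titled libraries. Where 1 library was set against 1, a gene was listed when its ratio of TPM + 1 was at least 2 and the higher value at least 5 TPM, with no test, and list medians were placed among 10000 random lists matched on mean expression. The random genes were drawn independently, so lists whose genes vary together can reach extreme percentiles with small medians. 35 gene lists with 692 entries, 674 of them matched, were fixed before the data were examined, as were the tests and most other settings. 34 lists had at least 5 tested members and were tested with limma's camera (preset inter-gene correlation of 0.01, and again estimated) and fry, adjusted over the lists. Further lists, chosen after the data were seen, appear in the closing section and in 1 figure.

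Named genes followed a fixed rule. For injected against PBS these were the 12 called genes with the largest rise and the 12 with the largest fall that lay on the same side in the Ad and Sy arms, had an arm mean of at least 5 TPM and a symbol that is not an identifier. For each pair of libraries they were the 10 highest and 10 lowest ratios. For each list up to 4 members were named, those called with the largest change or else those with the highest mean. Prg4, Tnfaip6, Il1b, Il6, Tnf, Mmp3, Mmp13, Adamts5, Col2a1, Acan, Cd163, S100a8, S100a9, Il10, Cxcl1 and Ccl2 were named whatever their values. Some genes that the rule picks are not used here.

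The test was tried on simulated data built from the 13371 genes. With 200 changed genes, 26% of those with a log2 change of 1 and 75% of those with a log2 change of 2 were recovered, and 0.98% of calls were false. With 4000 changed genes out of 13370, recovery was 86.5% and 97.2% and 3.55% of calls were false. Camera called 0 of 100 unchanged lists and 10 of 10 shifted lists. The changed genes were drawn only from genes well above the filter in the PBS libraries, so recovery of genes near 1 TPM was not tried. The simulated genes varied independently of each other. This therefore does not show how camera treats lists whose genes vary together, or what share of limma calls is then false.

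The alternatives were other scalings (median-ratio RLE factors, upper quartile), no filter on low values, a pseudocount of 0.1, the title arm as a block, each library left out in turn, other floors and ratios for the pairs, and exchanged PBS libraries. Where a library was left out, its arm kept 1 library, which limma then assumed to vary like the other arm.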

Results

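Messenger RNA was measured in 4 bulk libraries of synovium, the tissue that lines the joint, from rats with osteoarthritis. The AdMSC library (AdMSC 1) came from tissue that had received human AdMSCs and the SyMSC library (SyMSC 1) from tissue that had received human SyMSCs. These are the labels' abbreviations for human mesenchymal stem cells from different sources, commonly adipose tissue and synovium, and the labels do not spell them out. The other libraries, PBS 1 and PBS 2, came from tissue injected with PBS, a salt buffer. Tissue was taken on the day after the cells were injected; the interval for PBS was not given in the sources used here. The titles place PBS 1 with AdMSC 1 (the Ad arm) and PBS 2 with SyMSC 1 (the Sy arm). The values were TPM, length-normalised shares of each library's transcripts, over 17899 rat genes, so the read depth of each library is unknown and no counting interval can be given. Between 12582 genes (SyMSC 1) and 13155 genes (PBS 1) reached 1 TPM. The most abundant gene was the lysozyme gene Lyz2 in AdMSC 1 (19301 TPM) and in SyMSC 1 (27210 TPM), the hemoglobin gene Hba1 in PBS 1 (20161 TPM) and Sparc, which encodes a matrix glycoprotein, in PBS 2 (12856 TPM). Nothing in the labels says that the libraries came from separate animals, so p-values measure the spread between these libraries alone, which may be technical. Arm values are given as mean ± SD over n = 2 libraries, and log2 changes are on the log2(TPM + 1) scale, which understates the change of low genes.

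The first comparison asked how synovium that had received human cells of either source differed from synovium that had received PBS. With camera and a preset correlation, 10 gene lists were called higher, among them neutrophil, monocyte and macrophage and acute cytokine genes. Another 11 were called lower, among them collagen, sublining fibroblast, endothelial, mural, skeletal muscle and adipocyte genes. With camera and an estimated correlation 0 lists were called (2 at an unadjusted p under 0.05). Csf3r (gene ID 298518), the receptor for the neutrophil growth factor G-CSF, stood at 478 ± 84.95 TPM after injection and 8.23 ± 4.96 TPM with PBS (log2 change 5.80, SE 0.44, limma adjusted p = 0.00179). Spp1 (gene ID 25353), which encodes the secreted protein osteopontin, rose from 199.6 ± 9.80 to 8212 ± 2559.6 TPM (log2 change 5.32, SE 0.22, limma adjusted p = 0.000187). Tnmd (gene ID 64104), a marker of tendon cells, fell from 89.1 ± 39.4 to 1.10 ± 0.198 TPM (log2 change -5.35, SE 0.32, limma adjusted p = 0.000413). Angptl1 (gene ID 679942) fell from 186 ± 1.25 to 4.15 ± 1.84 TPM (log2 change -5.23, SE 0.25, limma adjusted p = 0.000239).

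Of 13371 genes tested with limma, 6476 passed an adjusted p of 0.05, with 3173 higher and 3303 lower after injection, and 3107 of them changed at least 2-fold (1347 higher, 1760 lower). The called genes were 48.4% of those tested, and 49.0% of them were higher. The counts of called list members below are to be read beside these shares. The 12 largest rises by the rule for named genes were Stfa2 (6.45), Nos2 (6.19), Cxcl2 (5.98), Cxcl3 (5.88), Mcemp1 (5.86), Csf3r, Il1r2 (5.75), Cxcr2 (5.64), Clec4e (5.37), Spp1, Osm (5.10) and Ifit1bl (5.09), given as log2 changes. Nos2 encodes inducible nitric oxide synthase, Cxcl2 and Cxcl3 are neutrophil chemoattractants, Cxcr2 is their receptor, and Osm is a cytokine of the interleukin 6 family. The 12 largest falls were Tnmd, Angptl1, C1qtnf3 (-5.21), Cldn11 (-4.92), Mlana (-4.84), Cytl1 (-4.77), Sult1a1 (-4.45), Pvalb (-4.39), Capn6 (-4.35), Itgbl1 (-4.28), Uts2r (-4.13) and Fndc1 (-4.08). Cldn11 encodes a tight junction protein and Pvalb a calcium-binding protein of fast muscle fibres. Stfa2 and Ifit1bl belong to families of similar genes, among which reads can be divided, so their values are uncertain. Some limma calls ended when 1 library was left out (adjusted p given). Nos2 was lost without PBS 1 (0.0655) or PBS 2 (0.0543), and Cxcl2 without AdMSC 1 (0.115), SyMSC 1 (0.157), PBS 1 (0.155) or PBS 2 (0.102). Il1r2 was lost without AdMSC 1 (0.0598) or SyMSC 1 (0.0742), and Cxcr2 without SyMSC 1 (0.0569). Clec4e was lost without PBS 1 (0.1) or PBS 2 (0.0823), and Fndc1 without PBS 1 (0.0712). The injected arm joins 2 cell sources, so its spread holds any difference between them.

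**Figure D1:**
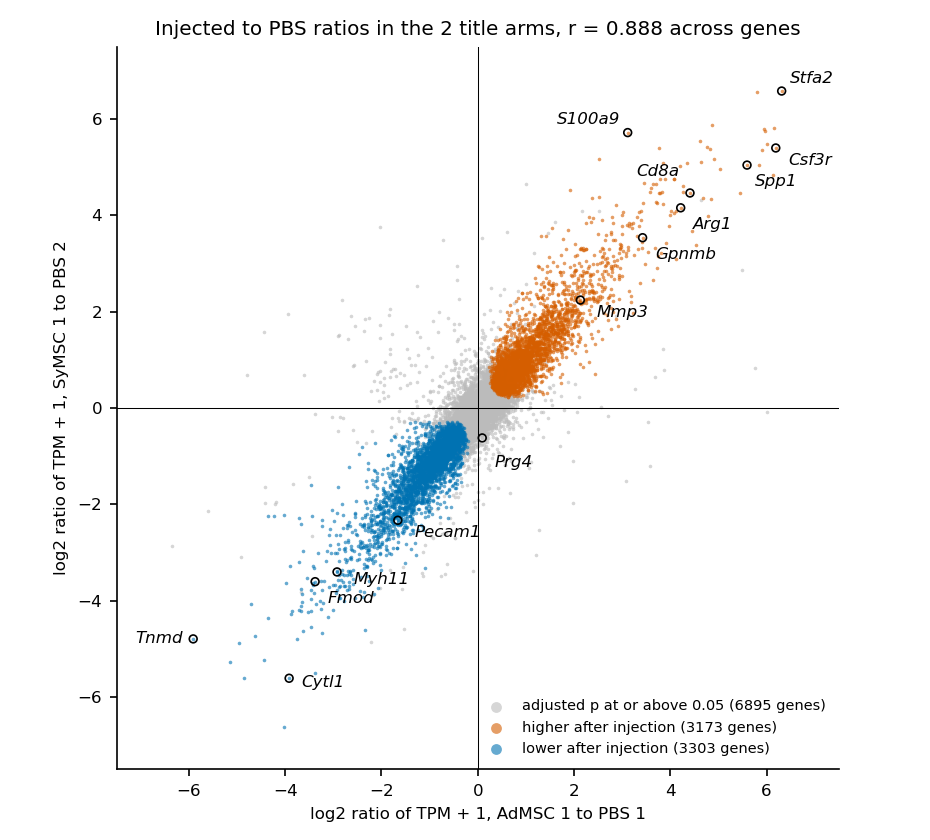
Each point is 1 of the 13371 tested genes, with the log2 ratio of AdMSC 1 to PBS 1 on the x axis and of SyMSC 1 to PBS 2 on the y axis, both on TPM + 1. Orange points are the 3173 genes called higher and blue points the 3303 genes called lower by limma over all 4 libraries; the ratios lie along the diagonal (r = 0.888 across genes), with Stfa2, Csf3r and Spp1 at the upper right and Tnmd and Cytl1 at the lower left.

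Among leukocyte genes, 8 of 18 neutrophil genes rose (9 adjusted over the list alone) and 10 did not pass. They included Csf3r, Il1r2 and Cxcr2. The alarmin genes S100a8 and S100a9, abundant in neutrophils and monocytes, rose from 70.1 ± 55.7 to 888 ± 368 TPM and from 62.3 ± 48.7 to 1183 ± 478 TPM. Of 19 monocyte and macrophage genes, 16 rose and 3 did not pass (17 adjusted over the list alone). The integrin gene Itgam stood at 2.94, the Fc receptor gene Fcgr1a at 2.86, the scavenger receptor gene Msr1 at 2.51 and the signalling adaptor gene Tyrobp at 2.34. T and NK cell genes rose in 9 of 15 cases, fell in 1 and did not pass in 5 (10 and 1 adjusted over the list alone). Cd8a went from 4.46 ± 0.375 to 117 ± 11.5 TPM, beside Cd8b (3.49), Cd2 (3.04) and Klrb1a (1.79). Dendritic cell and MHC class II genes rose in 8 of 15 cases, fell in 1 and did not pass in 6 (9 and 1 adjusted over the list alone). Those that rose included Itgax (2.64), Ccr7 (1.56) and the antigen loading genes RT1-DMa (1.62) and RT1-DMb (1.59). Mast cell genes went the other way: 5 of 8 fell and 3 did not pass (6 adjusted over the list alone). They included the tryptase genes Tpsb2 (-1.52) and Tpsab1 (-1.49), the transcription factor gene Gata2 (-1.88) and Hpgds (-1.07). With camera and a preset correlation, adjusted p was 0.000223 for neutrophil, 4.18e-08 for monocyte and macrophage, 0.00463 for T and NK cell, 0.00974 for dendritic cell and 0.00743 for mast cell genes. Each of these calls was lost with camera and an estimated correlation, where the adjusted p was 0.538 for all 5 lists. Single limma calls ended without 1 library (adjusted p given). Il1r2 was lost without AdMSC 1 (0.0598) or SyMSC 1 (0.0742), and Cxcr2 without SyMSC 1 (0.0569). S100a8 was lost without AdMSC 1 (0.164) or SyMSC 1 (0.217), and S100a9 without AdMSC 1 (0.135) or SyMSC 1 (0.178). Itgax was lost without PBS 1 (0.0787) or PBS 2 (0.139), and Ccr7 without AdMSC 1 (0.0682) or SyMSC 1 (0.114). Tpsb2 was lost without PBS 2 (0.102), and Hpgds without AdMSC 1 (0.0902), SyMSC 1 (0.162) or PBS 2 (0.0828). Ccr7 stayed called without PBS 2, with a log2 change of 0.996. With the title arm as a block, limma no longer called Itgax (adjusted p = 0.0585) or Hpgds (0.0643).

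Genes of resident synovial macrophages divided, with 6 of 16 higher, 6 lower and 4 that did not pass (6 and 7 adjusted over the list alone). The chemokine receptor gene Cx3cr1 (3.61), Siglec1 (1.88) and the mannose receptor gene Mrc1 (1.22) rose, and Gas6 (-2.02), a bridging ligand for dying cells, fell. Cd163, a hemoglobin scavenger receptor of macrophages, stood at 10.5 ± 1.32 TPM after injection and 16.5 ± 4.39 TPM with PBS (log2 change -0.59, SE 0.21, limma adjusted p = 0.0567) and did not pass. It passed in limma with the title arm as a block (adjusted p = 0.031) and without PBS 1 (-0.85, adjusted p = 0.0187). The list as a whole was not called (camera adjusted p = 0.72; adjusted p = 0.945 with an estimated correlation), and its median (-0.45) and mean (0.08) differed in sign, with a camera direction of lower. Of 7 B and plasma cell genes, Blnk rose (1.99), Fcmr fell (-1.09) and 5 did not pass (1 higher and 1 lower adjusted over the list alone; camera adjusted p = 0.275; adjusted p = 0.583 with an estimated correlation). Erythroid and platelet genes, a marker of blood in the tissue, were not called (camera adjusted p = 0.419; adjusted p = 0.863 with an estimated correlation). Of 10 genes 9 did not pass and 1 fell, the platelet integrin gene Itga2b (-0.98), with 1 lower adjusted over the list alone. Hba1 differed more between the PBS libraries (20161 and 7064 TPM) than between the injected ones (4918 and 10295 TPM). Without PBS 2 the erythroid list was called lower, with a median of -1.32. Its median was -1.12 without SyMSC 1, but above 0 without AdMSC 1 (0.02) or PBS 1 (0.14). With 1 library left out, some limma calls ended, at the adjusted p given. Itga2b was lost without AdMSC 1 (0.0606).

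Acute cytokine genes rose in 13 of 16 cases, fell in 1 and did not pass in 2 (13 and 2 adjusted over the list alone). Il1b went from 4.83 ± 1.63 to 118 ± 82.1 TPM, Il6 from 1.36 ± 0.431 to 42.8 ± 22.01 TPM, Nos2 from 0.980 ± 0.707 to 158 ± 108 TPM, and Arg1, the arginase that competes with nitric oxide synthase for arginine, from 6.44 ± 0.311 to 135 ± 9.42 TPM. Tnfaip6, a hyaluronan-binding protein induced in inflammation, rose from 40.8 ± 2.26 to 137 ± 31.4 TPM. Tnf was low in every library, listed at 0 in AdMSC 1 and at 2.52, 1.40 and 2.41 TPM in SyMSC 1, PBS 1 and PBS 2, and did not pass (limma adjusted p = 0.513). Without SyMSC 1, limma called it lower (adjusted p = 0.0209), but the injected value is then the 0 of AdMSC 1 alone, so that change is set by the added 1. Il10 was below the filter, with 0.83 TPM in AdMSC 1, 2.35 in SyMSC 1, 0 in PBS 1 and 0.96 in PBS 2. The cytokine list was called higher (camera adjusted p = 3.32e-05; adjusted p = 0.538 with an estimated correlation). Feedback genes of NF-kB rose in 9 of 18 cases, fell in 2 and did not pass in 7 (11 and 2 adjusted over the list alone). The apoptosis inhibitor gene Birc3 stood at 1.81, the mitochondrial superoxide dismutase gene Sod2 at 1.76, the ribonuclease gene Zc3h12a at 1.41 and the adhesion molecule gene Vcam1 at -1.69. That list lay near the threshold (camera adjusted p = 0.048; adjusted p = 0.583 with an estimated correlation) and was no longer called without SyMSC 1 (0.129) or under median-ratio (RLE) scaling (0.0771). Some limma calls ended when 1 library was left out (adjusted p given). Il1b was lost without PBS 1 (0.12) or PBS 2 (0.0968), and Nos2 without PBS 1 (0.0655) or PBS 2 (0.0543). Zc3h12a was lost without PBS 1 (0.0955).

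Chemokine genes moved both ways, with 10 of 22 higher, 4 lower and 8 that did not pass (10 and 4 adjusted over the list alone). The neutrophil chemoattractants led the rise: Cxcl1 went from 1.13 and 4.87 TPM in the PBS libraries to 45.5 and 74.5 TPM in AdMSC 1 and SyMSC 1, Cxcl3 from 1.18 ± 1.15 to 125 ± 58.1 TPM and Cxcl6 from 1.17 ± 0.0283 to 59.95 ± 44.8 TPM. Ccl2, a monocyte chemoattractant, rose from 78.7 ± 11.02 to 462 ± 28.9 TPM (log2 change 2.54, SE 0.15, limma adjusted p = 0.000267), and Ccl3 from 21.5 ± 13.1 to 437 ± 366 TPM. The chemokine list was not called (camera adjusted p = 0.27; adjusted p = 0.538 with an estimated correlation). Interferon response genes were also called both ways, with 5 of 30 higher, 8 lower and 17 that did not pass (5 and 8 adjusted over the list alone). Over all tested genes 48.4% were called, 49.0% of them higher, so these counts do not set the list apart. Ifit1 (4.04), Ifit3 (3.23), Oas3 (2.30) and Oasl (2.10) showed the 4 largest changes, all rises. This list was not called (camera adjusted p = 0.468; adjusted p = 0.904 with an estimated correlation), its median (-0.14) and mean (0.03) differed in sign, and its camera direction was lower. It was called lower without PBS 2, where its median was -0.48. That median was -0.35 without SyMSC 1, but above 0 without AdMSC 1 (0.04) or PBS 1 (0.16). Of the complement genes, C4b (-2.42), C1s (-2.19) and Serping1 (-2.33) fell and the receptor gene C3ar1 rose (2.03). In this list 4 of 18 members rose, 6 fell and 8 did not pass (4 and 6 adjusted over the list alone). It was not called (camera adjusted p = 0.194; adjusted p = 0.538 with an estimated correlation). MHC class I genes showed 5 rises and 2 falls among 15, and 8 did not pass (7 and 2 adjusted over the list alone). Nlrc5 stood at 0.92, Psmb8 at 0.52, RT1-S3 at -0.69 and RT1-T24-4 at -1.21. The list was not called (camera adjusted p = 0.109; adjusted p = 0.583 with an estimated correlation) except without AdMSC 1 (0.0249) and with no filter on low values (0.0496). Single limma calls ended without 1 library (adjusted p given). Cxcl1 was lost without AdMSC 1 (0.0623) or SyMSC 1 (0.0768), and Cxcl6 without PBS 1 (0.116) or PBS 2 (0.112). Ccl3 was lost without AdMSC 1 (0.0596), SyMSC 1 (0.112), PBS 1 (0.246) or PBS 2 (0.181), and Ifit1 without PBS 1 (0.0506). Ifit3 was lost without SyMSC 1 (0.0902), PBS 1 (0.124) or PBS 2 (0.193), and Oasl without PBS 1 (0.0516) or PBS 2 (0.0981). Nlrc5 was lost without SyMSC 1 (0.108) or PBS 1 (0.0671), and RT1-S3 without AdMSC 1 (0.109) or PBS 1 (0.126). Psmb8 was lost without SyMSC 1 (0.0685), PBS 1 (0.102) or PBS 2 (0.0682). The title arm as a block ended the limma calls of Ifit3 (adjusted p = 0.0543), Oasl (0.0525) and RT1-S3 (0.0543). The RT1, Ifit and Oas genes have close paralogs, so their values are uncertain.

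Genes of glycolysis and the response to low oxygen rose almost together, 18 of 19, and 1 did not pass (18 adjusted over the list alone). The glucose transporter gene Slc2a1 went from 18.5 ± 0.629 to 211 ± 20.8 TPM (log2 change 3.44, SE 0.13, limma adjusted p = 0.000161). The oxygen sensor gene Egln3 (3.46), the glycolytic regulator gene Pfkfb3 (3.20) and the hexokinase gene Hk2 (2.05) rose as well. Proliferation genes rose in 25 of 26 cases and did not pass in 1 (26 adjusted over the list alone). Examples are Rrm2, which supplies deoxynucleotides for DNA synthesis (2.34), the mitotic kinase genes Plk1 (2.08) and Cdk1 (1.85) and the replication helicase gene Mcm5 (1.97). Genes for the uptake of dying cells and lipid handling rose in 13 of 20 cases, fell in 5 and did not pass in 2 (14 and 5 adjusted over the list alone). Gpnmb, a glycoprotein of lipid-laden macrophages, went from 396 ± 40.6 to 4419 ± 206 TPM, Fabp5 from 119 ± 2.62 to 1293 ± 9.16 TPM. The lipid droplet gene Plin2 (3.01) and the oxidised lipid receptor gene Olr1 (2.82) rose. Oxidative phosphorylation genes rose by less, 9 of 21, and 12 did not pass (8 adjusted over the list alone). Cox5a stood at 0.74, Uqcrfs1 at 0.64, Cs at 0.59 and Atp5f1b at 0.52. With camera the adjusted p was 7.38e-09 for glycolysis, 3.56e-09 for proliferation, 0.00434 for the uptake list and 0.0274 for oxidative phosphorylation. With camera and an estimated correlation the adjusted p was 0.538 for each of the 4 lists. Without PBS 1 the oxidative phosphorylation list was not called (camera adjusted p = 0.0937). With 1 library left out, some limma calls ended, at the adjusted p given. Cs was lost without PBS 1 (0.0661), and Atp5f1b without AdMSC 1 (0.067), PBS 1 (0.0595) or PBS 2 (0.0766).

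Among stress and translation genes no list was called with the main settings. Immediate early genes rose in 4 of 20 cases, fell in 3 and did not pass in 13 (4 and 3 adjusted over the list alone). Zfp36 (1.86), which destabilises cytokine messages, Junb (1.84) and Ier2 (1.32) rose and the nuclear receptor gene Nr4a1 fell (-1.10). The list's median (-0.06) lay below 0, its mean (0.18) and its camera direction above (adjusted p = 0.836; adjusted p = 0.947 with an estimated correlation). Heat shock and unfolded protein genes rose in 7 of 18 cases, fell in 2 and did not pass in 9 (7 and 2 adjusted over the list alone). The pseudokinase gene Trib3 (2.11), Sdf2l1 (1.45) and the chaperone gene Hsph1 (0.97) rose and the small heat shock protein gene Hspb1 fell (-1.74). The list was not called (camera adjusted p = 0.127; adjusted p = 0.538 with an estimated correlation). Ribosomal protein genes did not pass in 26 of 28 cases. Rps4x (-0.68) and Rps19 (-0.64) fell (also 2 adjusted over the list alone; camera adjusted p = 0.0731; adjusted p = 0.709 with an estimated correlation). It was called lower without PBS 1 (camera adjusted p = 0.0226), under upper quartile scaling (0.0492), with the title arm as a block (0.0359) and when scaled without the 100 most abundant genes (0.0472). Some limma calls ended when 1 library was left out (adjusted p given). Ier2 was lost without SyMSC 1 (0.0823) or PBS 1 (0.0707), and Trib3 without PBS 2 (0.0715).

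Of 12 marker genes of lining fibroblasts, 7 fell, 3 rose and 2 did not pass (8 and 3 adjusted over the list alone). Clic5 fell from 68.4 ± 7.24 to 4.11 ± 0.0141 TPM and the protease gene Htra4 from 592 ± 112 to 39.2 ± 6.28 TPM. Hbegf fell (-1.72), and the hyaluronan synthase gene Has2 rose (1.88). Prg4, which encodes the joint lubricant lubricin, did not pass, with 3319.9 ± 1233 TPM after injection and 3848 ± 117 TPM with PBS (log2 change -0.26, SE 0.26, limma adjusted p = 0.438). It was called lower in limma without AdMSC 1 (log2 change -0.65). SyMSC 1 (2448 TPM) lay below both PBS libraries (3930 and 3765 TPM), and AdMSC 1 (4192 TPM) lay above them. Of 16 marker genes of sublining fibroblasts, 12 fell, 1 rose and 3 did not pass (12 and 1 adjusted over the list alone). Among them were Clec3b (-3.95), Dpt (-3.35), Smoc2 (-2.79) and the eosinophil chemoattractant gene Ccl11 (-2.61). Collagen and matrix genes fell in 15 of 25 cases, rose in 1 and did not pass in 9 (17 and 1 adjusted over the list alone). The collagen-binding proteoglycan gene Fmod went from 646 ± 106 to 57.1 ± 15.9 TPM. Col14a1 stood at -3.41, the elastin gene Eln at -3.09 and Col6a3 at -2.05. With camera the adjusted p was 0.0235 for lining, 0.000252 for sublining and 0.000107 for collagen genes. With camera and an estimated correlation the adjusted p was 0.538, 0.538 and 0.541. Single limma calls ended without 1 library (adjusted p given). Eln was lost without PBS 1 (0.0513) or PBS 2 (0.0638), and Smoc2 without AdMSC 1 (0.0523) or SyMSC 1 (0.0799).

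Of 14 chondrocyte genes, 10 fell and 4 did not pass (12 lower adjusted over the list alone). Comp, a cartilage and tendon matrix protein, fell from 606 ± 62.6 to 65.5 ± 22.8 TPM, beside Cytl1, Cilp (-3.72) and Cilp2 (-3.59). Acan, the main cartilage proteoglycan, stood at 10.9 ± 6.07 and 36.3 ± 15.7 TPM and did not pass (log2 change -1.68, SE 0.52, limma adjusted p = 0.0651). It passed limma under RLE scaling (adjusted p = 0.0477), upper quartile scaling (0.0485), with the title arm as a block (0.00338) and without AdMSC 1 (0.036). Col2a1, the main cartilage collagen, was below the filter with 0.71 TPM in AdMSC 1, 2.50 in SyMSC 1, 0.58 in PBS 1 and 0.53 in PBS 2. Matrix protease genes rose in 10 of 22 cases, fell in 4 and did not pass in 8 (10 and 4 adjusted over the list alone). The stromelysin gene Mmp3 went from 572 ± 30.9 to 2606 ± 1.92 TPM (log2 change 2.19, SE 0.12, limma adjusted p = 0.000246). The collagenase gene Mmp13 went from 16.7 ± 8.11 to 146 ± 39.1 TPM. Adam8 (4.37) and Mmp10 (2.26) rose, and the osteoclast and fibroblast protease gene Ctsk fell (-2.77). The aggrecanase gene Adamts5 rose by less (0.53, SE 0.17, limma adjusted p = 0.0402). Bone cell genes fell in 5 of 9 cases and did not pass in 3, the fallers including Ibsp (-1.83), Dmp1 (-1.77) and Ctsk, while Spp1, which macrophages also express, rose (5 lower and 1 higher adjusted over the list alone). With camera the adjusted p was 1.74e-05 for chondrocyte genes (adjusted p = 0.538 with an estimated correlation). The protease list (0.0562; adjusted p = 0.538 with an estimated correlation) and the bone list (0.27; adjusted p = 0.538 with an estimated correlation) were not called by camera. The protease list passed without PBS 1 (camera adjusted p = 0.0204), under upper quartile scaling (0.0498), with no filter on low values (0.0287) and when scaled without the 100 most abundant genes (0.0472). In limma, Adamts5 was lost without SyMSC 1 (0.178), PBS 1 (0.135) or PBS 2 (0.0912). It was also lost under upper quartile scaling (0.0604), with no filter on low values (0.0639) and when scaled without the 100 most abundant genes (0.0506).

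Genes of blood vessels were lower after injection. Of 17 endothelial genes, 16 fell and 1 did not pass (17 adjusted over the list alone). The adhesion molecule gene Pecam1 went from 159 ± 20.03 to 39.4 ± 8.15 TPM, with Cldn5 at -2.41, Emcn at -2.16 and Vwf at -2.08. All 15 genes of mural and smooth muscle cells fell (15 adjusted over the list alone). The smooth muscle myosin gene Myh11 went from 108 ± 33.7 to 10.9 ± 0.926 TPM, with the calponin gene Cnn1 at -2.95, Lmod1 at -2.60 and Mylk at -2.57. With camera the adjusted p was 4.18e-08 for endothelial and 7.37e-08 for mural genes, and the adjusted p was 0.538 for both with an estimated correlation. Wnt and Notch genes fell in 10 of 21 cases, rose in 1 and did not pass in 10 (10 and 1 adjusted over the list alone). They include the Wnt antagonist genes Sfrp2 (-3.48) and Dkk3 (-2.97), the Notch target gene Heyl (-2.07) and Fzd8 (-1.81). The camera adjusted p was 0.00856, and the adjusted p was 0.541 with an estimated correlation. Growth factor genes divided, with 6 of 26 higher, 13 lower and 7 that did not pass (6 and 16 adjusted over the list alone). The bone morphogenetic protein antagonist gene Grem1 (3.14), Angptl4 (3.23) and the activin subunit gene Inhba (2.60) rose and Tgfb3 fell (-2.24). The list was not called (camera adjusted p = 0.109; adjusted p = 0.627 with an estimated correlation). With 1 library left out, some limma calls ended, at the adjusted p given. Sfrp2 was lost without SyMSC 1 (0.0726), PBS 1 (0.053) or PBS 2 (0.0827), and Angptl4 without AdMSC 1 (0.0632) or SyMSC 1 (0.0853). Inhba was lost without PBS 1 (0.162) or PBS 2 (0.186).

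Some lists hold markers of tissues that lie beside the synovium. Skeletal muscle genes fell in 7 of 15 cases and did not pass in 8 (10 adjusted over the list alone). Pvalb went from 148 ± 57.5 to 5.84 ± 0.502 TPM, with the creatine kinase gene Ckm at -3.12, Myl1 at -3.31 and Actn3 at -3.24. The muscle list was also unequal between the PBS libraries, with a median log2 ratio of PBS 2 to PBS 1 of -1.71. Adipocyte genes fell in 8 of 21 cases and did not pass in 13 (7 adjusted over the list alone). They included Plin4 (-2.72), the insulin-responsive glucose transporter gene Slc2a4 (-2.52), the adipocyte transcription factor gene Pparg (-2.17) and Fabp4 (-1.95). Their median log2 ratio of PBS 2 to PBS 1 was 1.35. Schwann cell and nerve genes fell in 7 of 13 cases, rose in 1 and did not pass in 5 (7 and 1 adjusted over the list alone). Egfl8 (-1.50) and Sox10 (-1.39) fell and the neuregulin receptor gene Erbb3 (1.65) rose. The keratinocyte list had 2 tested genes and no list test, with Sfn at -0.20 and Pkp1 at -0.10, neither past the threshold (limma adjusted p = 0.538 and 0.788). With camera the adjusted p was 4.14e-05 for muscle, 0.02 for adipocyte and 0.0298 for nerve genes. With camera and an estimated correlation the adjusted p was 0.538, 0.647 and 0.538. The adipocyte list was not called without AdMSC 1 (camera adjusted p = 0.0703) or PBS 2 (0.0919). Some limma calls ended when 1 library was left out (adjusted p given). Myl1 was lost without AdMSC 1 (0.131) or SyMSC 1 (0.0997), and Actn3 without AdMSC 1 (0.238) or SyMSC 1 (0.246). Ckm was lost without AdMSC 1 (0.205) or SyMSC 1 (0.185), and Plin4 without AdMSC 1 (0.0663) or SyMSC 1 (0.0543). Fabp4 was lost without AdMSC 1 (0.243) or SyMSC 1 (0.217). Fabp4 stayed called without PBS 2, with a log2 change of -1.28. Over all lists, camera called 21 of 34 with the preset correlation (10 higher, 11 lower) and 0 with an estimated correlation, of which 2 had an unadjusted p under 0.05. The fry test, which does not compare a list with other genes, called 9 in a direction and 33 for change either way.

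**Figure D2:**
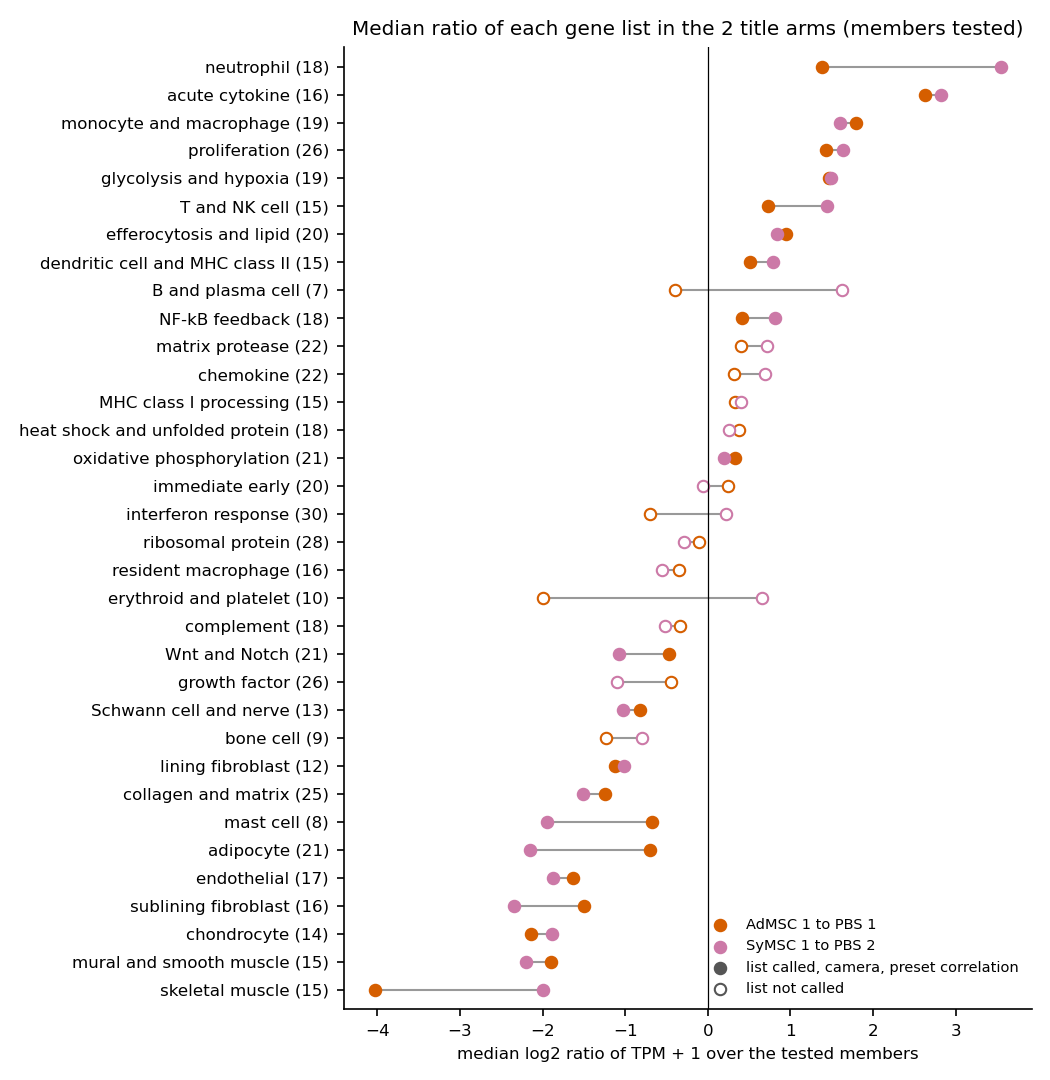
Each row is 1 of the 34 tested gene lists with its number of tested genes, and the x axis is the median log2 ratio of TPM + 1 over them, orange for AdMSC 1 to PBS 1 and pink for SyMSC 1 to PBS 2. Filled points mark the 21 lists called by camera with the preset correlation; the acute cytokine list lies at 2.63 and 2.83, the mural list at -1.89 and -2.20, and the erythroid list on opposite sides of 0 at -1.99 and 0.65.

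**Figure D3:**
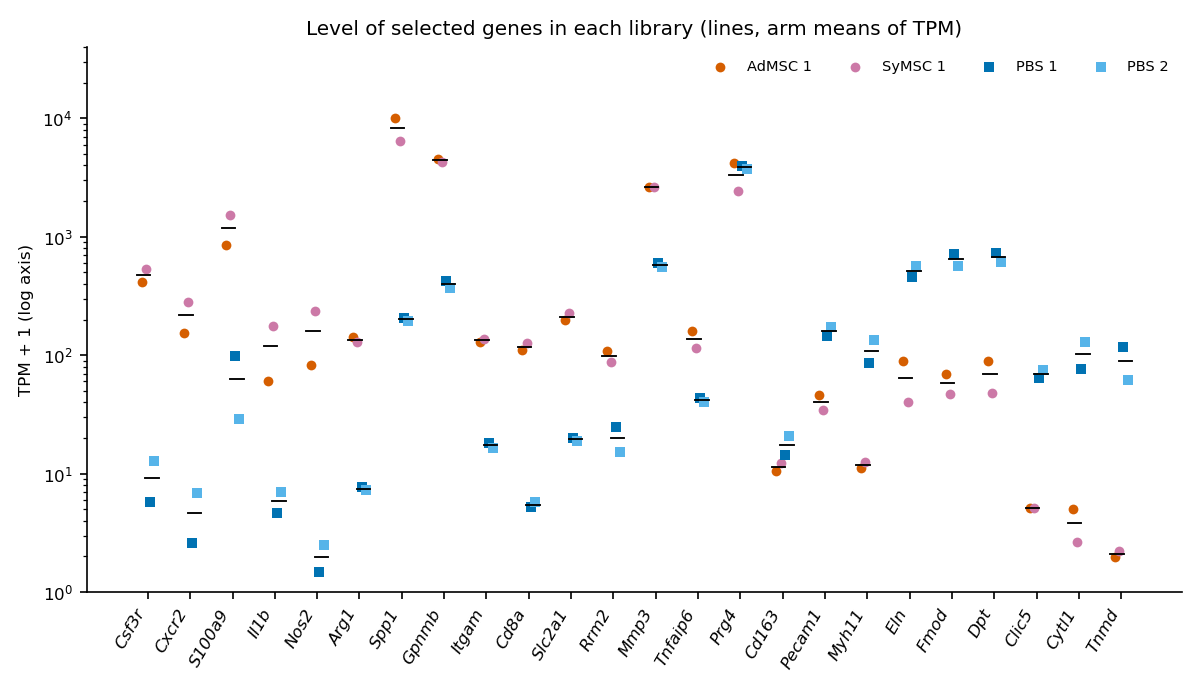
The y axis is TPM + 1 on a log scale for 24 named genes, with 1 point per library (circles, injected; squares, PBS) and short lines at the arm means of n = 2. Injected and PBS points are apart for Spp1 (10022 and 6402 against 207 and 193 TPM) and for Tnmd (0.960 and 1.24 against 117 and 61.2 TPM), and overlap for Prg4.

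The AdMSC library was then set against the PBS library of the Ad arm. The largest ratios were those of Stfa2 (log2 ratio 6.31), Csf3r (6.19), Cxcl2 (6.16), Il1r2 (6.004), Mcemp1 (5.96), Cxcl3 (5.95), Cxcr2 (5.91), Nos2 (5.81) and Spp1 (5.59), beside Stfa2l2 with 42.95 TPM in AdMSC 1. The lowest ratios were those of Kera, a corneal and tendon proteoglycan gene (-6.35), Tnmd (-5.91), the fast myosin gene Myh4 (-5.61), C1qtnf3 (-5.15), Cldn11 (-4.97), the lymphatic chemokine gene Ccl21 (-4.92), Angptl1 (-4.85), the cartilage gene Chad (-4.79) and Pvalb (-4.72). Natd1, at 25.3 TPM in PBS 1, was listed at 0 in the other libraries. Stfa2l2 was listed at 0 in PBS 1, and Kera and Myh4 were lower in PBS 2 (20.4 and 6.67 TPM) than in PBS 1 (118 and 74.96 TPM). In all, 1205 genes were at least 2-fold higher and 1328 at least 2-fold lower, 2533 of 10839 genes with at least 5 TPM in either library. Against 10000 random lists of like expression, the list median in this pair lay at the 100th percentile for cytokine (2.63), monocyte and macrophage (1.79), glycolysis (1.47) and neutrophil genes (1.39). It lay at percentile 0 for endothelial (-1.63), mural (-1.89), chondrocyte (-2.14) and skeletal muscle genes (-4.03). The muscle median was -1.99 in the Sy arm, and muscle genes were lower in PBS 2 than in PBS 1 (-1.71). Between PBS 2 and PBS 1, monocyte and macrophage (median 0.15) and endothelial genes (0.13) also lay at percentiles 99.4 and 99.2. Glycolysis (13.2) and chondrocyte genes (83.2) did not lie as far out. An extreme percentile alone therefore does not mark an effect of treatment. With 1 library on each side there is no replicate check and no test. In limma with 3 groups, where the lone injected library is assumed to vary like the PBS pair (1 residual degree of freedom), AdMSC differed from both PBS libraries in 4600 genes (2392 higher, 2208 lower). With no filter on low values it called 0 of 17889 genes (5816 at an unadjusted p under 0.05).

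The SyMSC library was compared in the same way with the PBS library of the Sy arm. Stfa2 (6.59), Nos2 (6.57), the pattern receptor gene Clec4e (5.87), Cxcl2 (5.81), Cxcl3 (5.80), Mcemp1 (5.75), S100a9 (5.72), Il1r2 (5.49) and Ifit1bl (5.42) were among the highest log2 ratios. Cytl1 (-5.61), Angptl1 (-5.61), the sulfotransferase gene Sult1a1 (-5.51), C1qtnf3 (-5.28), Mlana (-5.23), Cldn11 (-4.88), Itgbl1 (-4.81), Tnmd (-4.80), Clec3b (-4.67) and the urotensin receptor gene Uts2r (-4.64) had the lowest. The list medians were 2.83 for cytokine, 3.54 for neutrophil and 1.60 for monocyte and macrophage genes, each at the 100th percentile of random lists. They were -2.34 for sublining fibroblast, -2.20 for mural and -2.15 for adipocyte genes, each at percentile 0. The adipocyte median was -0.70 in the Ad arm, and adipocyte genes were higher in PBS 2 than in PBS 1 (1.35). The limit on percentiles given for the Ad arm holds here too. Here 1393 genes were at least 2-fold higher and 1634 at least 2-fold lower, 3027 of 10827. In the 3-group limma fit SyMSC differed from both PBS libraries in 5374 genes (2437 higher, 2937 lower). With no filter on low values it called 0 of 17889 (6285 at an unadjusted p under 0.05).

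The ratios of the Ad and Sy arms, which share no library, ran together. Across 13371 genes, which are not independent replicates, Pearson's r was 0.888 and Spearman's rho 0.886. Of the genes eligible in both arms, 991 were at least 2-fold higher in both, where 147.9 would be shared by independent lists, and 1145 were at least 2-fold lower in both, where 182.9 would be. In opposite directions, 3 and 17 genes moved 2-fold. Spp1 (5.59 and 5.05), Gpnmb (3.42 and 3.54), Arg1 (4.22 and 4.16), Cd8a (4.41 and 4.47) and Mmp3 (2.13 and 2.24) are examples of genes higher in both, and Cldn11 (-4.97 and -4.88) and Clic5 (-3.66 and -3.86) of genes lower in both, given as log2 ratios of the Ad and the Sy arm.

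The last comparison asked whether the cell sources differed. Higher in SyMSC 1 than in AdMSC 1 were the cartilage genes Chad (log2 ratio 3.74) and Ucma (2.38), the neutrophil collagenase gene Mmp8 (2.24), the chemokine genes Ccl21 (2.90) and Ccl6 (2.24), the leukocyte adhesion gene Jaml (2.33), and the broadly expressed genes Hprt1 (3.04) and Rabif (2.61). Lower in SyMSC 1 were Brms1 (-4.74), Ebna1bp2 (-4.55), Ppial4g (-2.32), the mast cell protease gene Mcpt1l1 (-2.30), the lipocalin gene Apod (-2.14), Gng13 (-2.10) and Cpxm1 (-1.90). Some of these genes also differed between PBS 2 and PBS 1: Chad (-1.74), Ebna1bp2 (-1.47), Mmp8 (-1.42), Hprt1 (-1.26) and Ccl21 (1.06). Rabif was listed at 0 in PBS 1 and at 20.8 TPM in PBS 2. The other genes above differed less than 2-fold between the PBS libraries. Brms1 and Ebna1bp2 stood at only 0.07 and 0.35 TPM in SyMSC 1. Neutrophil genes had a median ratio of 1.44 (100th percentile of random lists) against -0.59 between PBS 2 and PBS 1 (percentile 0), and collagen genes -0.50 (percentile 0) against -0.30 (percentile 0). In all, 224 genes differed at least 2-fold between the sources (150 higher and 74 lower in SyMSC 1), and 235 differed between the PBS libraries by the same rule (100 higher and 135 lower in PBS 2). The 3-group limma fit called 0 genes between the sources (861 at an unadjusted p under 0.05, smallest adjusted p = 0.254). For genes listed at 0 in either library no ratio is given. Casp6 had 6.94 TPM in SyMSC 1 and Ceacam4 9.69 TPM, and they were listed at 0 in AdMSC 1. Hist2h2aa3 had 11.9 TPM in AdMSC 1 and Ppp1r35 7.15 TPM, and they were listed at 0 in SyMSC 1. In PBS 1 and PBS 2, Casp6 stood at 9.45 and 7.69 TPM and Hist2h2aa3 at 36.43 and 22.98 TPM. Ceacam4 was listed at 0 in both PBS libraries. Ppp1r35 had 8.06 TPM in PBS 1 and was listed at 0 in PBS 2, so it parted by title as well as by source.

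The marker lists of blood, fat, muscle and interferon response differed between the PBS libraries, and the injected libraries differed the other way for all but fat. Erythroid genes were lower in PBS 2 than in PBS 1 (median log2 ratio -1.46, percentile 0) and higher in SyMSC 1 than in AdMSC 1 (1.16, 100th percentile). Adipocyte genes were higher in PBS 2 than in PBS 1 (1.35, 100th percentile) and in SyMSC 1 than in AdMSC 1 (0.28, 100th percentile). Skeletal muscle genes were lower in PBS 2 (-1.71, percentile 0) and higher in SyMSC 1 (0.16, percentile 99.9). The same held for interferon response genes (-0.53, percentile 0, and 0.14, 100th percentile). Between the Sy-titled and the Ad-titled libraries limma called 0 genes (33 at an unadjusted p under 0.05), in a fit that leaves treatment in its error. With treatment as a further term, added after the data were seen, limma called 1 gene (1085 at an unadjusted p under 0.05). This was LOC100909585, with 437 and 6216 TPM in SyMSC 1 and PBS 2 and 27.1 and 356 TPM in AdMSC 1 and PBS 1 (log2 difference 4.04, SE 0.10, limma adjusted p = 0.0257).

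**Figure D4:**
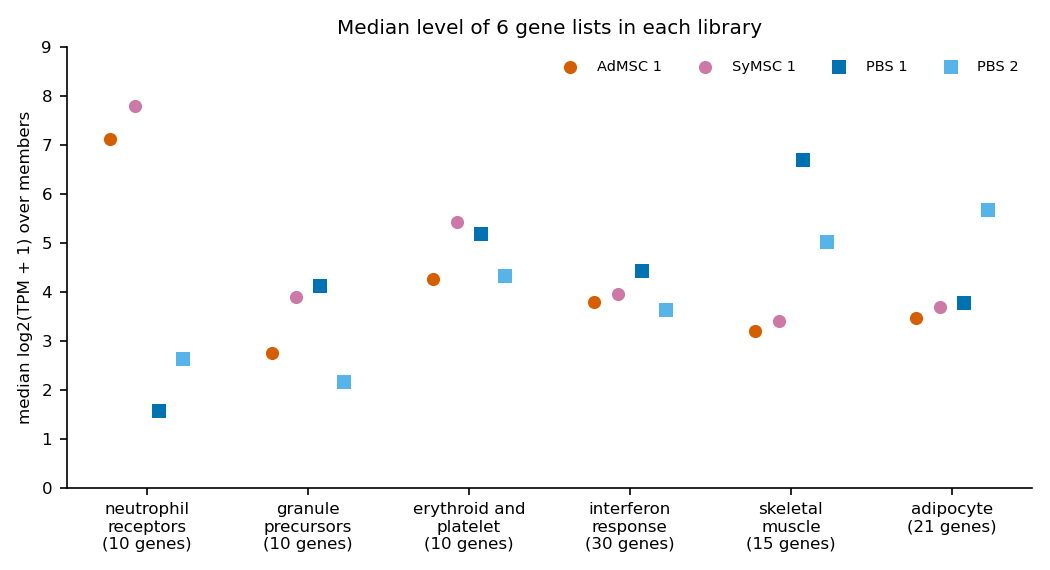
The y axis is the median log2(TPM + 1) over the members of 6 gene lists in each of the 4 libraries (circles, injected; squares, PBS). Neutrophil receptor genes are at 7.12 and 7.80 in the injected and 1.56 and 2.62 in the PBS libraries, while granule precursor and erythroid genes are higher in SyMSC 1 and PBS 1 than in AdMSC 1 and PBS 2; the receptor and precursor lists were chosen after the data were seen.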

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

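All tests in this part were chosen after the results were seen; intervals are 95% bootstrap intervals over list members, which are not independent replicates.

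In the leading pattern, seen with the preset correlation, leukocyte and cytokine lists were higher and stromal and vascular lists lower after injection. Human reads counted on rat genes can raise only genes that the injected cells express. Of 19 monocyte and macrophage genes, markers of leukocytes, 16 rose, with medians of 1.79 and 1.60 in the Ad and Sy arms. Between PBS 2 and PBS 1 their median was 0.15. These values argue against human MSC reads as the source of the rise of that list. For other genes that source stays open. Collagen and mural genes, which cultured MSCs express abundantly, were lower (median log2 change -1.67, interval -2.02 to -1.28, 40 genes). Their level with PBS (median 220 TPM) would still hide a small human share. A uniform dilution by incoming cells that express none of the resident genes would lower these genes by a common ratio. Instead the variance of changes was 8.85 times what the disagreement of the arms gives (interval 5.50 to 14.9). It was taken over 106 resident genes of at least 5 TPM in every library, on log2 TPM without a pseudocount. This argues only against dilution by cells that express none of these genes. Where incoming cells express some of them, dilution alone gives unequal changes, and such expression was not tested. Resident genes that rose, such as Has2 (1.88) and Erbb3 (1.65), also add to the variance. Dilution as the whole of the fall therefore stays open. Over all 148 resident genes on log2(TPM + 1) the ratio was 5.81, and by list it ran from 2.03 (chondrocyte) and 4.42 (skeletal muscle) to 102 (lining fibroblast). A few abundant genes do not account for the fall. Leaving the 100 most abundant genes out of the total shifted injected against PBS libraries by a log2 of at most 0.0459 (0.0281 to 0.0459 over 4 pairs). The smallest median fall among the stromal and vascular lists was 1.06. An effect of the injected cells and a difference between animals, in dissection or in the time since injection stay open and untested. The interval for PBS is not given, and 2 libraries per arm cannot separate these causes.

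In the second pattern the neutrophil list had a median above 0 in both arms (1.39 and 3.54) while the erythroid and granule precursor lists went opposite ways. The neutrophil list itself holds some precursor genes. Among these, Mpo had log2 ratios of -2.58 in the Ad arm and 0.90 in the Sy arm, and Camp -2.37 and 1.61. The neutrophil median in the Ad arm therefore covers members that fell there. Erythroid genes had a median log2 ratio of -1.99 in the Ad arm and 0.65 in the Sy arm, a difference of 2.64 that was not tested, and precursor genes such as Mpo and Camp -2.46 and 1.56, a difference of 4.02, also not tested. Marrow or blood of 1 make-up, carried into libraries in differing amounts, does not account for the neutrophil rise: in the 4 pairs of an injected and a PBS library the neutrophil median exceeded the erythroid median by at least 2.57 (interval 1.35 to 4.76). Blood of a changed make-up stays open for that rise; carried blood or marrow and the cell source stay open for the erythroid and precursor lists, where no test here decides. Erythroid genes were lower in PBS 2 than in PBS 1 (-1.46) and higher in SyMSC 1 than in AdMSC 1 (1.16), the former larger in size by 0.30 (interval 0.00127 to 0.51); precursor genes stood at -2.22 and 1.64, and that list was chosen on these data.

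The interferon list had a median of -0.70 in the Ad arm and 0.22 in the Sy arm, a difference of 0.92 that was not tested. PBS 2 lay below PBS 1 (-0.53) and SyMSC 1 above AdMSC 1 (0.14), with the former larger in size by 0.39 (interval 0.01 to 0.55). Still, 1 library on each side does not separate the cell source from a difference between the PBS libraries, and both stay open.

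Other results went opposite ways in the Ad and Sy arms. The B and plasma cell list had medians of -0.40 and 1.63, a difference of 2.03, and the immediate early list 0.24 and -0.05, a difference of -0.29; list differences were not tested. For single genes limma tested the difference of the arms and called 0 of 13371 (50 at an unadjusted p under 0.05), a fit that leaves treatment in its error, and 0 with treatment as a further term (359 at an unadjusted p under 0.05, 1 residual degree of freedom). None of the genes below passed; Ppial4g, below the filter, was not tested. Prg4 had log2 ratios of 0.09 and -0.62, a difference of -0.71, and Pkp1 0.01 and -0.22, a difference of -0.23. Chad had ratios of -4.79 and 0.69, a difference of 5.48, and Ucma -1.86 and 0.24, a difference of 2.10. For Hprt1 the ratios were -3.61 and 0.69 (difference 4.30), for Brms1 1.99 and -1.97 (-3.96), for Ebna1bp2 1.97 and -1.10 (-3.08), and for Ppial4g 1.79 and -0.23 (-2.03). Tnf, listed at 0 in AdMSC 1, was lower in the Ad arm and had a ratio of 0.05 in the Sy arm, and Rabif, listed at 0 in PBS 1, was higher in the Ad arm and had -0.04 in the Sy arm. Their differences on TPM + 1, 1.31 and -1.83, are set by the added 1 and are no measure of size, since a 0 has no known limit. No group had enough libraries for a search for single libraries out of line.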

How the results depend on the processing

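Alternatives added after the data were seen were a 2-fold minimum, scaling without the 100 most abundant genes, an estimated correlation, treatment as a term for the title split, and a pseudocount of 0.1 for the pairs and the agreement. The count of 6476 genes lay between 6060 and 6772 under RLE and upper quartile scaling, no filter, a pseudocount of 0.1, the title-arm block and scaling without the top 100 genes. Without 1 library it ranged from 4590 to 5379 (higher 2201 to 2423, lower 2230 to 2956), and the lists called from 20 to 22. A 2-fold minimum gave 3107 genes (1347 higher, 1760 lower), fewer by its construction. The median over all genes moved by at most 0.05 in log2 under any scaling, and the share called higher, 49.0%, lay between 44.8% and 52.3%. The 21 called lists became 0 with an estimated correlation; the cause was not tested.

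With the replicate block for title arm, 6590 genes were called (3250 higher, 3340 lower), 6176 of them shared with the fit without it, and 22 lists. Libraries of 1 title deviated little together over all genes (r = 0.117 across genes). Single genes still parted by title, such as LOC100909585 and Ppp1r35, so this value does not show that the titles share nothing. Nothing in the labels says that the titles mark shared animals or days.

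Pair counts fell by construction with a floor of 20 TPM or a 4-fold ratio. AdMSC against PBS 1 gave 1486 genes (760 higher, 726 lower) at the floor and 692 (337, 355) at 4-fold, SyMSC against PBS 2 gave 1762 (888, 874) and 988 (440, 548), and SyMSC against AdMSC 132 (93, 39) and 31 (20, 11). Between the PBS libraries the same rules gave 125 and 77. RLE scaling, a floor of 1 TPM, a pseudocount of 0.1 and the other PBS library kept the pair counts with an injected library within 1.5 times; PBS 2 against PBS 1 gave 398 at a floor of 1 TPM against 235. With no filter on low values, the 3-group fit called 0 genes for AdMSC and 0 for SyMSC against both PBS libraries (smallest adjusted p 0.0883 and 0.0691, limma); the cause was not tested. The count of 0 for SyMSC against AdMSC stayed at 0 under RLE scaling. The title split went from 0 to 1 gene with treatment as a further term, which takes treatment out of the error. The agreement of the arms was r = 0.860 with the PBS libraries crossed, 0.928 for genes with a mean of at least 20 TPM and 0.855 with a pseudocount of 0.1.

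Of 150 named genes past the threshold, 110 stayed past it without each library in turn and 40 did not in at least 1 case; 0 changed sign. In limma, other settings ended the calls of Cxcl2 and Ccr7 (pseudocount of 0.1, adjusted p 0.0662 and 0.0673), RT1-S3 and Hpgds (no filter, 0.0612 and 0.0796) and, with the block, of Itgax, RT1-S3, Hpgds, Ifit3 and Oasl (0.0525 to 0.0643). Not run, because they need counts, were the count models, the higher count minimum and the prior count; scaling by library size is what TPM already is. The table holds 1 unit, so the alternative unit did not apply. The unknown depth limits what can be said of genes near 1 TPM, and 2 libraries per arm limit everything else.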

Other observations

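The lists in this part were chosen after the data were seen, so their tests describe patterns already noticed. Some of their genes also stand in a list fixed beforehand: 6 of 10 neutrophil receptor, 4 of 10 granule precursor, 7 of 14 tendon, 3 of 17 elastic fibre, 2 of 14 integrated stress, 1 of 14 antioxidant and 1 of 15 pattern receptor genes. Genes of receptors for microbial and damage signals rose in all 15 tested cases (camera adjusted p = 7.96e-09 over 9 added lists; adjusted p = 0.28 with an estimated correlation). Tlr1 went from 1.39 ± 0.509 to 38.8 ± 7.90 TPM, Clec7a, a receptor for fungal glucans, from 28.6 ± 2.88 to 381 ± 131 TPM, and Tlr4, the endotoxin receptor gene, by a log2 change of 0.94. Antioxidant genes driven by NRF2, together with metallothioneins, rose in 11 of 14 cases (camera adjusted p = 2.9e-05; adjusted p = 0.218 with an estimated correlation), with the heme oxygenase gene Hmox1 from 81.5 ± 6.17 to 955 ± 206 TPM and Mt2A from 360.0 ± 48.9 to 1965 ± 5.82 TPM. Genes of the proton pump that acidifies lysosomes rose in 12 of 15 cases (camera adjusted p = 2.9e-05; adjusted p = 0.218 with an estimated correlation), led by Atp6v1b2 (2.32). Cholesterol synthesis and uptake genes rose in 9 of 17 cases and fell in 1 (camera adjusted p = 0.00374; adjusted p = 0.453 with an estimated correlation), with Sqle at 1.28. The integrated stress list was not called (camera adjusted p = 0.0642; adjusted p = 0.28 with an estimated correlation), though Cebpb rose from 76.9 ± 41.9 to 845 ± 322 TPM and Ddit4 by 2.37. Without 1 library, limma calls ended as follows (adjusted p given). Cebpb was lost without AdMSC 1 (0.0645) or SyMSC 1 (0.0964).

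Tendon and ligament genes fell in 11 of 14 cases (median log2 change -3.31; camera adjusted p = 2.21e-06; adjusted p = 0.218 with an estimated correlation). Igfbp6 went from 799 ± 29.5 to 61.1 ± 19.2 TPM and Thbs4 from 576 ± 249 to 119 ± 60.3 TPM. Elastic fibre genes fell in 10 of 17 cases and rose in 3 (camera adjusted p = 0.00374; adjusted p = 0.453 with an estimated correlation): the microfibril genes Mfap4 (2976 ± 147 to 249 ± 154 TPM) and Mfap2 (569 ± 71.1 to 35.8 ± 14.6 TPM) fell and Emilin2 rose (2.16). Neutrophil receptor genes rose in 9 of 10 cases (camera adjusted p = 1.52e-06; adjusted p = 0.28 with an estimated correlation), and granule precursor genes were not called (camera adjusted p = 0.867; adjusted p = 0.957 with an estimated correlation), with Cebpe the 1 of 10 that rose (2.01). Without 1 library, limma calls ended as follows (adjusted p given). Thbs4 was lost without SyMSC 1 (0.0839) or PBS 1 (0.101), and Mfap4 without PBS 1 (0.088) or PBS 2 (0.0876).

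The single genes given next were picked after their values were seen. Cd8a (4.44) and Cd8b (3.49) rose, as did the T cell receptor complex genes Cd3e (0.84) and Cd3g (1.20), and Cd4 fell (-0.63). The difference between these changes was not tested, and in rats CD8 is also found on NK cells and on some macrophages. In PBS 1 and PBS 2, Cd4 stood at 174 and 205 TPM, far above Cd3e (4.36 and 6.24 TPM). The fall of Cd4 therefore cannot be read as a loss of T cells, and which cells held its message was not tested. Among chemokines, the 4 that fell were the lymphocyte attractant gene Cxcl9 (-2.95), the stromal chemokine gene Cxcl12 (-2.61), Ccl24 (-2.64) and Cx3cl1 (-1.79), while the receptor of the last, Cx3cr1, rose (3.61). Interferon genes parted, the Ifit family among them, with Ifit1 (4.04) and Ifit3 (3.23) higher and Ifit2 (-1.09), Mx2 (-1.95) and Ifi44 (-1.70) lower. Among secreted tissue inhibitors of metalloproteases, Timp1 rose (1.91) and Timp2 (-0.78) and Timp3 (-2.15) fell. All of these passed the limma threshold over all genes. Without 1 library, limma calls ended as follows (adjusted p given). Cd3e was lost without SyMSC 1 (0.0854) or PBS 1 (0.0672), and Cd4 without PBS 2 (0.0828). Ifit1 was lost without PBS 1 (0.0506), and Ifit3 without SyMSC 1 (0.0902), PBS 1 (0.124) or PBS 2 (0.193). Mx2 was lost without AdMSC 1 (0.192) or SyMSC 1 (0.177). Ifit3 was also lost with the title arm as a block (0.0543). Mx2 stayed called without PBS 1, with a log2 change of -1.28.

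Of the 3 ways to part the 4 libraries into pairs, the split by treatment gave 6476 genes, the split by title 0 (33 at an unadjusted p under 0.05) and the crossed split 0 (50 at an unadjusted p under 0.05) in limma; 3 splits are too few for a share under 0.05. The title and crossed splits leave treatment in their error, and with treatment as a further term limma called 1 gene (1085 at an unadjusted p under 0.05) and 0 genes (359).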
